A study of Mus musculus with 2 samples.

How the data were processed

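Nuclei from mouse hippocampus were measured by droplet single-nucleus RNA sequencing in 2 libraries, 1 from wild-type mice injected with AAV-mCherry and 1 from wild-type mice injected with AAV-CD47, each taken 2 months after injection. AAV is an adeno-associated virus used to carry a gene into cells, and mCherry is a red fluorescent protein that serves as the control cargo. How many mice each library holds is not given in the sources used here. The protocol also names 5xFAD mice, which were not analysed here.

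The deposited tables hold raw UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) per gene and nucleus barcode, and every value is a whole number. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mouse build mm10 were used, with no further role stated. Whether intron reads were counted, which annotation release was used and how barcodes were chosen are not given in the sources used here. Both tables list the same 56884 genes, and 150 repeated symbols were kept apart by their gene identifiers. Of these identifiers, 91.32% were found in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, from which the coordinates were taken. The table for AAV-mCherry holds 12777 barcodes with 90959831 UMIs, and that for AAV-CD47 holds 11351 barcodes with 99140849 UMIs.

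Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept, which removed 83 nuclei of AAV-mCherry and 34 of AAV-CD47. Doublets, droplets with 2 nuclei, were scored by Scrublet in scanpy 1.11.5. Its automatic threshold did not work in AAV-mCherry, where at 0.653 it marked 1 nucleus, so the threshold of AAV-CD47, 0.174, was used for both. This choice was made after the data were examined; it removed 4.545% of the AAV-mCherry nuclei and 5.24% of the AAV-CD47 nuclei. Both libraries were then clustered together, with UMIs scaled to 10000 per nucleus and log-transformed, the 2000 most variable genes chosen within libraries, 50 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9), giving 37 clusters. Clustering had first been run with automatic doublet calls.

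Clusters were named from 24 marker lists fixed before the data were examined. The rule that applies them was set after cluster tables had been seen. A cluster took the class with the highest mean log2 fold over its markers (pseudocount 10 CPM) if at least 3 of these markers, and most of the list, were at least 2-fold higher than in the other nuclei and 1 was among its 10 leading genes. A cluster was left unnamed if another class had more markers among its 10 leading genes. It was also left unnamed if at least 4 markers of an unrelated class were at least 2-fold higher. Those had to be no fewer than the remaining markers of that list, with a mean log2 fold over the list of at least 1. This left 16 clusters unnamed, with 32.0% of the AAV-mCherry nuclei and 33.3% of the AAV-CD47 nuclei; clusters near the subicular or cortical excitatory list were among them. A class name therefore stands for nuclei that are like that cell type in these markers. Excitatory neurons pooled are the dentate granule, CA1 and CA2/CA3 classes.

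UMIs were summed per class and library and scaled to the total of that sum as CPM, computed here from the deposited counts. A gene was measured in a class with at least 50 UMIs over both libraries. Ratios are AAV-CD47 over AAV-mCherry, on the log2 scale or as folds, with exact conditional binomial 95% intervals. CPM values have exact Poisson 95% intervals and shares have exact Clopper-Pearson 95% intervals. All of these cover counting error only. With 1 library per group there is no replicate, so no test between groups was made and no p-value is given. A sum of 0 would be set to a floor of 3 counts.

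For 24 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile that describes these 2 libraries only. The range of a median over 1000 Poisson redraws of its counts is given as its counting range. A further list of sex-linked genes was read over all nuclei. The list genes Ddx58 and Scn2a1 and the marker Tmem2 were not found under those symbols. Which lists stand among the main results was decided after their values were seen.

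Genes named in the text follow a rule fixed before the data were examined. For microglia and pooled excitatory neurons it takes the 10 genes highest and the 10 lowest in AAV-CD47 by the interval bound nearest to a ratio of 1, and for inhibitory neurons, astrocytes, oligodendrocytes and oligodendrocyte precursors (OPCs) the 5 highest and 5 lowest. A ranked gene needed 20 CPM in the higher library and a class CPM at least 0.5 times that of all other nuclei there; mitochondrial, sex-linked and haemoglobin genes and gene models without a symbol were left out. The 4 members farthest from 1 were taken from each list in the class it was read in, and general lists were named in microglia and pooled excitatory neurons. Cd47, Sirpa, P2ry12, Cx3cr1, Apoe, Trem2, C1qa, Mertk and Gfap were always included. Some list members that the rule selects are not printed, among them genes that are withheld and not reported here. The interferon list of oligodendrocytes, and Fabp5, were chosen after their values were seen.

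The intervals were tested on simulated independent Poisson counts with 200 changed genes. This checks their calculation under counting error alone. It cannot show that they hold where the UMIs of a gene gather in some nuclei. In the simulation of the microglia comparison, over 7717 genes, the interval held the true ratio for 95.76% of unchanged genes, and it lay above 1 for 61.19% of genes raised 1.5-fold and 95.16% of those raised 2.0-fold. In the simulation of pooled excitatory neurons, over 18824 genes, these shares were 95.61%, 95.08% and 100.00%.

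The alternatives fixed before the data were examined were no filter on nuclei, at least 1000 UMIs per nucleus, doublets kept, Leiden resolution 0.5, libraries clustered separately, unnamed clusters left out of the denominator, the mean of single-nucleus CPM, the median ratio of each class set to 1, nuclei thinned to 1000 UMIs, a minimum of 200 UMIs per gene and mitochondrial genes left out of totals. Further ones were chosen after seeing the data: automatic doublet thresholds, mixed clusters put in their nearest class, excitatory classes weighted equally, and each gene's log2 ratio minus its median over the other classes. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.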

Results

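Single-nucleus RNA profiles of hippocampus were compared between wild-type mice that had received AAV-mCherry, the control virus, and mice that had received AAV-CD47, 2 months earlier. CD47 is a membrane protein that restrains engulfment by binding SIRPα on phagocytes, and the series title ties its neuronal form to microglial phagocytosis and autism-like behaviour. Each group is 1 library. After filtering, AAV-mCherry held 12117 nuclei with a median of 5428 UMIs and 2562 genes, and AAV-CD47 held 10724 nuclei with a median of 7092.5 UMIs and 3248 genes. There are no replicates, so every difference below compares these 2 libraries, has no replicate check, and carries an interval for counting error only. Y-linked Ddx3y was read at 43.7 CPM in AAV-mCherry and 47.3 CPM in AAV-CD47, while Xist was read at 1.69 CPM and 0.439 CPM. The width between the 10th and 90th percentiles of the log2 ratios of all measured genes was 1.499 in excitatory neurons, 1.25 in inhibitory neurons, 1.37 in astrocytes, 1.24 in oligodendrocytes, 1.34 in OPCs and 1.56 in microglia.

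Cd47 was higher in the library labelled AAV-CD47. Over all kept nuclei it stood at 156.7 CPM in AAV-mCherry (95% interval 154.0 to 159.4) and 365.4 CPM in AAV-CD47 (361.5 to 369.4), a ratio of 2.33 (2.29 to 2.38). The gene (ENSMUSG00000055447) lies on the plus strand of chromosome 16, from 49800533 to 49915010 in GRCm38. Among 10 named classes the widest gap was in CA2/CA3 neurons, with 162.5 CPM against 690.1 CPM, a ratio of 4.25 (4.04 to 4.47). There, 53.2% of AAV-CD47 nuclei held at least 10 Cd47 UMIs (49.0% to 57.2%) against 0.587% of AAV-mCherry nuclei, at median depths of 17003 and 17055 UMIs. In inhibitory neurons these shares were 7.54% and 1.55%, at median depths of 10160 and 11824 UMIs. Dentate granule neurons had a ratio of 2.36 and CA1 neurons one of 2.06. In classes outside the excitatory neurons the ratio was 1.78 in inhibitory neurons, 1.72 in astrocytes, 1.66 in oligodendrocytes, 2.14 in OPCs and 1.72 in microglia, so Cd47 UMIs were also more frequent in glia. Whether RNA of the virus is counted under this gene is not given in the sources used here, so these values do not separate it from the native transcript. Nuclear-encoded genes of oxidative phosphorylation, described below, had a higher median ratio than Cd47 in each of these classes except pooled excitatory neurons and CA2/CA3 neurons.

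**Figure D1:**
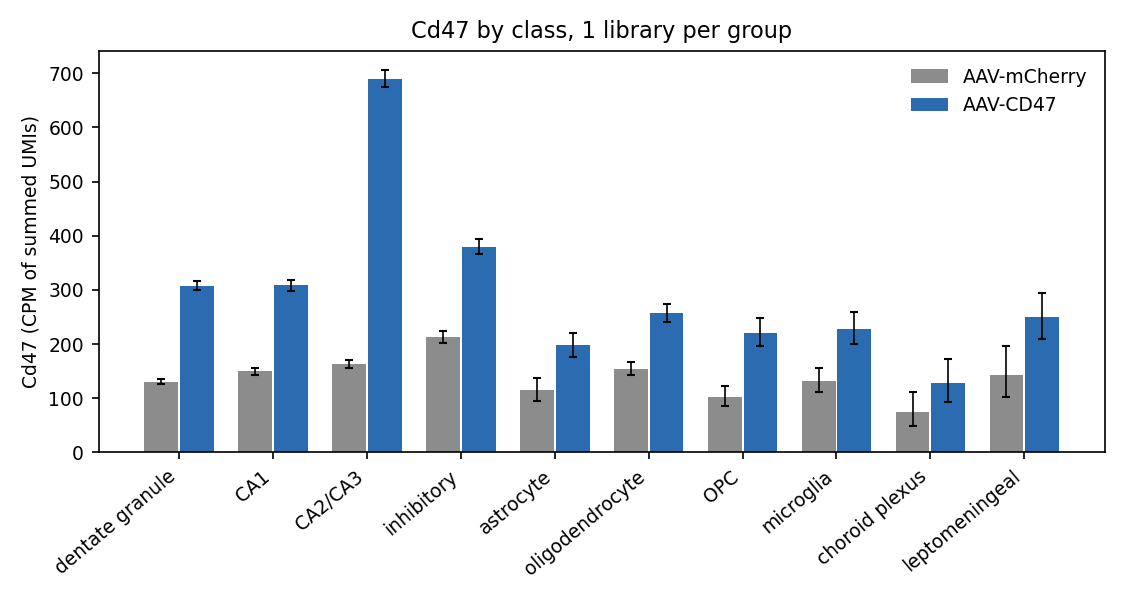
Cd47 in CPM of summed UMIs (vertical axis) for 10 classes (horizontal axis), with grey bars for AAV-mCherry, blue bars for AAV-CD47 and error bars for exact Poisson 95% intervals. The blue bar is the higher one in every class, and CA2/CA3 neurons reach 690.1 CPM.

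The make-up of the libraries differed. Excitatory neurons of the hippocampus were 38.9% of AAV-mCherry nuclei (38.02% to 39.8%) and 32.6% of AAV-CD47 nuclei (31.8% to 33.5%), a gap that, among the named classes, lay in dentate granule neurons, at 25.01% and 18.6%. CA1 neurons were at 8.25% and 8.60% and CA2/CA3 neurons at 5.62% and 5.47%, with overlapping intervals. Inhibitory neurons were at 4.27% in AAV-mCherry and 6.93% in AAV-CD47, astrocytes at 2.72% and 4.80%, and OPCs at 2.15% and 2.96%. Oligodendrocytes were at 12.7% and 11.2%, a log2 ratio of -0.19 that was -0.02 with the libraries clustered separately. Microglia, the resident phagocytes of the brain, were at 4.23% (3.88% to 4.61%) and 4.57% (4.18% to 4.98%), with overlapping counting intervals. Leptomeningeal cells were at 0.735% and 1.42%, choroid plexus cells at 0.652% and 0.877%, and immature neurons at 0.396% and 0.14%. Clusters left unnamed although nearest to a class held further nuclei: 0.784% and 0.504% for microglia, 0.801% and 0.709% for oligodendrocytes, 0.149% and 0.205% for astrocytes, and 0.743% and 3.11% for CA1 neurons. Unnamed clusters nearest to subicular or cortical excitatory neurons held 0.982% and 4.73% in cluster 16, 2.154% and 3.04% in cluster 25, and 1.04% and 1.25% in cluster 27, so the gap in excitatory neurons holds for the named classes only. A cluster whose AAV-mCherry nuclei had a median of 588 UMIs made up 18.2% of AAV-mCherry and 0.429% of AAV-CD47. With at least 1000 UMIs per nucleus the log2 ratio of the microglial share moved from 0.11 to -0.17, that of excitatory neurons from -0.25 to -0.53, that of oligodendrocytes from -0.19 to -0.41, that of inhibitory neurons from 0.70 to 0.42 and that of astrocytes from 0.82 to 0.54.

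**Figure D2:**
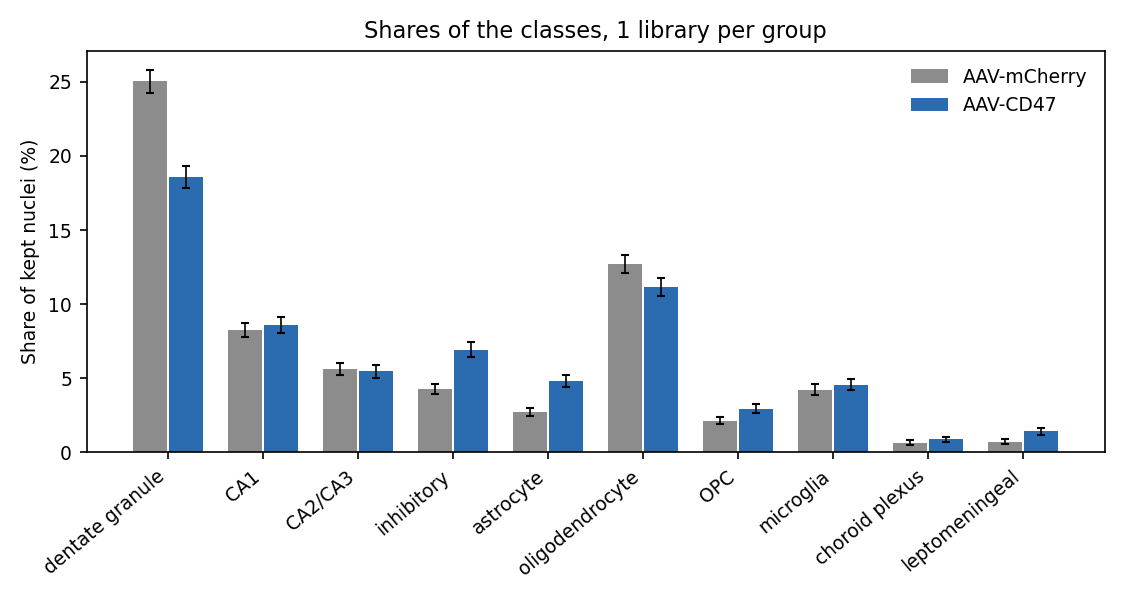
Share of kept nuclei in percent (vertical axis) for 10 classes (horizontal axis), grey for AAV-mCherry and blue for AAV-CD47, with exact Clopper-Pearson 95% intervals. Dentate granule neurons are 25.01% and 18.6%, and astrocytes are 2.72% and 4.80%.

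In microglia, genes of the disease-associated state were lower in AAV-CD47. The median log2 ratio of 20 measured members was -0.84 (counting range -1.10 to -0.68), at percentile 0.00 of random lists, and 13 members were at least 1.5-fold lower and 1 at least 1.5-fold higher. Gpnmb, a glycoprotein of lipid-laden phagocytes (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), stood at 105.3 CPM from 113 UMIs in AAV-mCherry and at 0.997 CPM from 1 UMI in AAV-CD47, a log2 ratio of -6.72 (-12.04 to -4.22). Apoe, which carries lipids between cells (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), stood at 919.9 CPM and 236.2 CPM, a log2 ratio of -1.96 (-2.17 to -1.75). Igf1, a growth factor, had 77 UMIs and 3 UMIs, and Axl, a receptor for dying cells, had 67.1 CPM and 15.9 CPM. Of the 20 members 6 were above a ratio of 1, among them Trem2, a lipid-sensing receptor, at 389.6 CPM and 446.5 CPM, and Fabp5, a fatty acid binding protein chosen after its values were seen, at 96.9 CPM and 148.5 CPM. With a minimum of 200 UMIs per gene, which leaves out low members such as Gpnmb and Igf1, the median was -0.39. In AAV-mCherry 28 of 513 microglial nuclei, or 5.46%, held a Gpnmb UMI, against 7.03% of the deeper excitatory neurons; per UMI, all other nuclei had 7.58 CPM of Gpnmb in AAV-mCherry and 2.78 CPM in AAV-CD47, so it was lower outside microglia too. UMIs of border macrophage markers in the microglia class were 30 in AAV-mCherry and 4 in AAV-CD47, those of dentate granule markers stood at 2584 CPM and 1637 CPM, those of oligodendrocyte markers at 666.4 CPM and 540.2 CPM, and those of B cell markers at 129.5 CPM and 250.1 CPM. The B cell list includes Ebf1, also a leading gene of an unnamed cluster nearest to endothelial cells.

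Genes that present antigen were also lower in microglia. The list had a median log2 ratio of -0.60 (-0.94 to -0.44, percentile 0.24), with 4 of 8 measured members at least 1.5-fold lower and none at least 1.5-fold higher. Cd74, the chaperone of MHC class II, had 151 UMIs and 4 UMIs, a log2 ratio of -5.14 (-7.04 to -3.76); it was detected in 13.6% of AAV-mCherry microglia and 0.816% of AAV-CD47 microglia, against 0.7% and 0.4% of excitatory neurons, at median depths of 1772 and 1935 UMIs in microglia and 8764.5 and 9672 UMIs in excitatory neurons. Nlrc5, a regulator of MHC class I, had a log2 ratio of -2.00, H2-Q7 one of -2.32 and H2-D1 one of -0.71. The interferon list had a median of -0.52, with Stat2 at -1.10, Parp14 at -0.58 and Bst2 at 0.20.

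Homeostatic microglial genes were higher, with a median log2 ratio of 0.49 (0.42 to 0.59, percentile 99.39); 7 of 16 were at least 1.5-fold higher and none at least 1.5-fold lower. The median was 0.30 with nuclei thinned to 1000 UMIs and 0.34 with doublets kept. Cst3, a protease inhibitor, had a log2 ratio of 1.15, against a median of 1.09 over the other classes, Olfml3 one of 0.82, Tmem119 one of 0.75 and Siglech one of 0.72. The purine receptor P2ry12 stood at 988.8 CPM and 1505 CPM, and the fractalkine receptor Cx3cr1 at 888.2 CPM and 1139 CPM. Over the members that other classes also measured, the median relative to those classes was 0.03.

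The phagocytosis list as a whole differed little between the microglia of the 2 libraries. Its median log2 ratio was -0.17 (-0.21 to 0.01, percentile 14.58), and 21 of 23 measured members lay within 1.5-fold. The engulfment receptor Mertk stood at 1523 CPM and 1440 CPM, and Sirpa, the receptor of CD47, at 1016 CPM and 941.8 CPM, with intervals of both ratios that include 1. The member farthest from 1 was Axl, also in the disease-associated list, with a log2 ratio of -2.07, while Dock2, Dock1 and Was, which act on the actin skeleton, had -0.45, -0.58 and -1.06. The lysosome list was at -0.06, with Ctsb at -0.66, Ctsl at 0.47 and Laptm5 at 0.31. Complement genes had a median of 0.32, with C1qa at 0.35, C1qb at 0.38 and C1qc at 0.52. Over the members that other classes also measured, among them Csmd1 and Csmd2, the median relative to those classes was -0.40. Csmd1 and Csmd2, members of this list that neurons express strongly, were at -2.32 and -2.02. The cytokine and NF-kB list was at 0.03, with Nfkb1 at -0.42, Il18 at 0.10, Nlrp3 at 0.40 and Il1a at 0.66, and the CD47-SIRPα list at -0.24, with Itgav at -0.36, Ptpn11 at -0.33 and Itgb3 at -0.15. Relative to the other classes the ratios of C1qb, C1qc, Ctsl and Nfkb1 changed sign. All other nuclei held C1qb at only 5.09 CPM and 5.34 CPM and C1qc at 4.09 CPM and 4.22 CPM. The values subtracted for C1qb and C1qc therefore rest on low levels.

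Among all ranked genes of microglia, the lowest in AAV-CD47 were Gpnmb, Cd74, Igf1, Rftn1, Marchf3, Apoe, Ccnd3, Reln, Myo5a and St8sia6. Rftn1, a protein of lipid rafts, stood at 192.9 CPM and 26.9 CPM, and Ccnd3, a cyclin, at 988.8 CPM and 289.0 CPM. Reln stood at 57.8 CPM and 9.97 CPM, against 69.4 CPM and 106.4 CPM in all other nuclei. The highest were Ndufb4, Ndufa4, Rpl9, Ndufaf8, Myl12b, Atp5mpl, H2az1, Cox5a, Cox6c and Atp5k, most of them genes of the respiratory chain, and these were also higher in the other classes, where the medians of Cox5a and Cox6c were 1.69 and 1.67. Ndufa4, for example, had a log2 ratio of 1.84 in microglia and a median of 1.72 over the other classes.

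**Figure D3:**
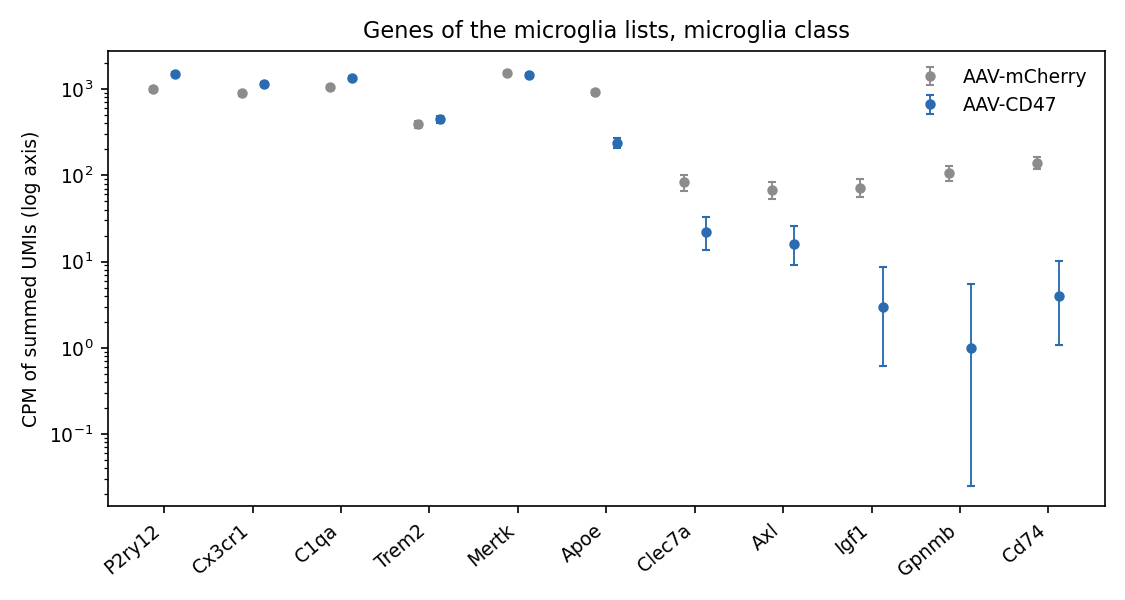
CPM of summed UMIs on a log axis (vertical) for genes of the microglia lists and Cd74 (horizontal) in the microglia class, grey for AAV-mCherry and blue for AAV-CD47, with exact Poisson 95% intervals. Gpnmb stands at 105.3 CPM and 0.997 CPM, while Mertk stands at 1523 CPM and 1440 CPM.

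In pooled excitatory neurons the median log2 ratio of all measured genes was 0.10, and list medians are given relative to it after the raw value. Random lists matched on expression, which the percentiles use, had medians below that of all genes here. These were -0.084 for the excitatory synapse list and -0.051 for the autism risk list. Excitatory synapse genes had a median of -0.20 (-0.22 to -0.17, percentile 4.02), or -0.30 relative to all genes, and 28 of 30 members lay within 1.5-fold. The scaffold Shank2 stood at 317.5 CPM and 205.5 CPM, the NMDA receptor subunit Grin2a at 3952 CPM and 2788 CPM, and the adhesion protein Lrrtm2 at 27.6 CPM and 44.0 CPM. Autism risk genes were at -0.10 (percentile 21.39), or -0.21 relative to all genes, with 45 of 49 within 1.5-fold. Among them Tbr1 was at 1.02, Adnp at 0.91 and Setbp1 at -0.66. Tbr1 stood at only 6.97 CPM and 14.1 CPM, against 12.9 CPM and 28.3 CPM in all other nuclei. Adnp stood at 8.01 CPM and 15.1 CPM, against 13.3 CPM and 11.25 CPM in all other nuclei. Relative to the other classes the medians of both lists turned positive, at 0.16 and 0.02.

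Presynaptic genes had a median of 0.12 (percentile 98.56), or 0.015 relative to all genes, led by the vesicle protein Vamp2 at 1.21 and Cplx2 at 0.72, with Erc2 at -0.49. Inhibitory synapse genes were at 0.22 (percentile 98.99), or 0.12 relative to all genes. Among them the chloride exporter Slc12a5 was at 0.53, Gabra5 at 0.49, Nlgn2 at 0.48 and Slc32a1 at 1.25. Slc32a1 stood at only 1.99 CPM and 4.74 CPM here, against 64.8 CPM and 72.4 CPM in all other nuclei, so carried-over RNA may contribute. Ion channel genes were at -0.13 (percentile 37.09, random median -0.103), or -0.24 relative to all genes. Among them Kcnq3 was at -0.71, Kcnd3 at -0.50, Cacna1c at -0.48 and Kcna2 at 0.79. Guidance and adhesion genes were at -0.16 (percentile 22.76, random median -0.11), or -0.26 relative to all genes. Among them Slit1 was at -0.60, Nrp1 at -0.58, Cdh13 at -0.56 and Cntn6 at 1.03. Cntn6 stood at 7.43 CPM and 15.2 CPM, against 134.4 CPM and 128 CPM in all other nuclei. Both lists thus lay close to random lists matched on expression. Both list medians turned positive relative to the other classes, at 0.03 and 0.12. The ratios of Grin2a, Gabra5, Cacna1c and Nrp1 changed sign there.

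Activity-regulated genes were higher in excitatory neurons, with a median log2 ratio of 0.53 (0.46 to 0.59, percentile 99.76), or 0.43 relative to all genes; 8 of 20 were at least 1.5-fold higher and none at least 1.5-fold lower. The early transcription factors Jun, Junb and Egr3 were at 0.96, 1.05 and 0.79, and Ier2 at 1.44. Genes that signal from neurons to microglia had a median of 0.54, or 0.44 relative to all genes. Among them Bsg was at 0.93, Cd200 at 0.80 and Cx3cl1 at 0.55 beside Cd47 at 1.51. These genes were also higher elsewhere, with medians over the other classes of 0.57, 0.53, 0.35 and 0.79. In inhibitory neurons this list was at 0.45. The CD47-SIRPα list, at 0.19, or 0.09 relative to all genes, held Itgav at 0.43, Sirpa at 0.19, which was -0.16 relative to the other classes, and Ptpn11 at 0.16. Genes of heat shock and dissociation stress were at 0.93 (percentile 100), or 0.83 relative to all genes, with Hspe1 at 1.68, Hspa1b at 1.42, Hsp90aa1 at 0.96 and Hsp90ab1 at 0.96, and cholesterol synthesis genes at 0.79 (percentile 99.99), or 0.69, with Hmgcs1 at 1.39, Fdps at 1.31 and Idi1 at 1.27. Antigen presentation was at 0.87, or 0.77 relative to all genes, with B2m at 0.87 and Ciita at -1.95. The interferon list was at 0.23, or 0.13, and the apoptosis list at 0.17, or 0.07, with Bbc3 at 1.25, Bax at 0.95 and Bcl2 at -0.44. Of the genes named here, Ier2, Hspa1b, Fdps, Idi1, Ciita, Bbc3 and Bcl2 were below 20 CPM in both libraries.

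The genes highest in excitatory neurons of AAV-CD47 were Myl12b, Spcs1, Rpl36al, Rpl9, Ndufa4, Cirbp, Cox8a, Nop10, Rps10 and Atp5mpl, with log2 ratios from 1.73 to 2.07. Those lowest were Slc15a2, Csmd2os, Gins2, Tnfrsf25, Chd7, Chst9, Mid1, Zmym1, Dscaml1 and Angpt2; relative to the other classes Csmd2os and Angpt2 were at 0.024 and 0.23. Slc15a2, a peptide transporter, stood at 46.1 CPM and 12.4 CPM, and Dscaml1, an adhesion protein, at 778.2 CPM and 395.2 CPM. Most of these nuclei came from clusters that held nearly 1 library each. Dentate granule neurons lay in cluster 0, with 3009 AAV-mCherry and 43 AAV-CD47 nuclei, and cluster 22, with 22 and 1949, while CA1 neurons lay in cluster 5, with 947 and 56, and cluster 6, with 53 and 866.

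In inhibitory neurons, whose median ratio of all genes was 0.13, the highest genes in AAV-CD47 were Ndn, Myl12b, Tac2, Tomm7 and Atp5k, and the lowest were Pde10a, Slc15a2, Alkal2, Mid1 and Grip1os1. Tac2, which encodes neurokinin B, stood at 11.3 CPM and 45.7 CPM, and Pde10a, a phosphodiesterase, at 1480 CPM and 542.5 CPM. Inhibitory synapse genes there had a median of 0.04, or -0.09 relative to all genes, with 21 of 21 within 1.5-fold.

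In astrocytes Apoe was higher in AAV-CD47, at 2400 CPM and 3763 CPM, a log2 ratio of 0.65 (0.58 to 0.72), or 0.17 relative to the other classes. The reactive list had a median of -0.33 over 6 measured members, with a counting range of -0.56 to 0.09; Gfap, the intermediate filament of reactive astrocytes, stood at 130.1 CPM and 98.6 CPM, C4b at 130.1 CPM and 71.5 CPM, Stat3 at 96.4 CPM and 70.9 CPM, and Tnc at 74.9 CPM and 126.8 CPM. The homeostasis list was at -0.05, with Mfge8 at 0.63, Mertk at -0.53 and Slc1a3 at -0.32. The ratios of Gfap and Slc1a3 changed sign with automatic doublet thresholds, and that of Slc1a3 was 0.001 relative to the other classes. The highest genes were Tmsb10, Pigyl, Ppia, Cox6c and Atp5md, and the lowest were Pde10a, Vit, Etnppl, Slc24a4 and Lhfp. Etnppl, an enzyme of phospholipid metabolism, stood at 217.1 CPM and 42.1 CPM. Pde10a stood at 678.3 CPM and 40.9 CPM, against 819.2 CPM and 462.3 CPM in all other nuclei. Slc24a4 stood at 58.0 CPM and 8.42 CPM, against 103.3 CPM and 60.1 CPM. For Pde10a and Slc24a4, carried-over RNA may contribute.

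In oligodendrocytes interferon-response genes were lower in AAV-CD47. Their median log2 ratio was -1.29 (-1.67 to -0.86, percentile 0.00), and 6 of 9 measured members were at least 1.5-fold lower. Bst2 had 58 and 5 UMIs, Oasl2 51 and 5, and Ifit3 56 and 8. Myelin genes were at -0.15 (percentile 41.31), with Mobp at -0.60, Nfasc at -0.46, Mbp at -0.43 and Opalin at 0.50; this median was 0.17 with automatic doublet thresholds, and the ratios of Nfasc and Opalin changed sign relative to the other classes. UMIs of dentate granule markers in this class stood at 3133 CPM and 2440 CPM. The lowest ranked genes were Zbtb16, Gli2, Sgk1, P4ha1 and Adipor2; the stress-responsive kinase Sgk1 stood at 214.9 CPM and 45.9 CPM. The highest were Ndufa4, Cox5a, Atp5l, Fuom and Myl12b, the last at -0.24 relative to the other classes. These nuclei too lay in clusters of nearly 1 library, cluster 15 with 1486 AAV-mCherry and 92 AAV-CD47 nuclei and cluster 32 with 19 and 1085. In OPCs the highest were Ndufb8, Rpl41, Sst, Cox5a and Cox6c and the lowest Hs6st3, Nr4a3, Csmd2os, Ndst3 and Ankrd33b; the ratio of Hs6st3 changed sign at resolution 0.5 and that of Ndst3 with doublets kept.

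Nuclear genes of oxidative phosphorylation were higher in AAV-CD47 in every class with a value, while relative to the other classes the median turned to -0.015 in inhibitory neurons, -0.08 in astrocytes, -0.16 in oligodendrocytes and -0.02 in microglia, and was 0.11 in excitatory neurons. The median log2 ratio was 1.40 in excitatory neurons (29 of 30 members at least 1.5-fold higher), 1.33 in inhibitory neurons, 1.29 in astrocytes, 1.22 in oligodendrocytes, 1.44 in OPCs and 1.23 in microglia, each at percentile 100. Over all nuclei, UMIs of 86 ribosomal protein genes stood at 5765 CPM and 11310 CPM, and mitochondrial genes at 6186 CPM and 8485 CPM, while the nuclear RNA Malat1 stood at 45900 CPM and 43970 CPM. In microglia, the heat shock and dissociation stress list was at 0.35, which turned to -0.10 relative to the other classes, with Hspe1 at 1.67, Hspa8 at 0.70, Dnaja1 at 0.51 and Hsp90aa1 at 0.37, the cholesterol list at 0.67, with Fdps at 1.56, and the apoptosis list at 0.31, with Apaf1 at -0.75, Bcl2l1 at -0.46, Bax at 0.58 and Bcl2 at 0.75; Dnaja1, Hsp90aa1 and Bax changed sign relative to the other classes.

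**Figure D4:**
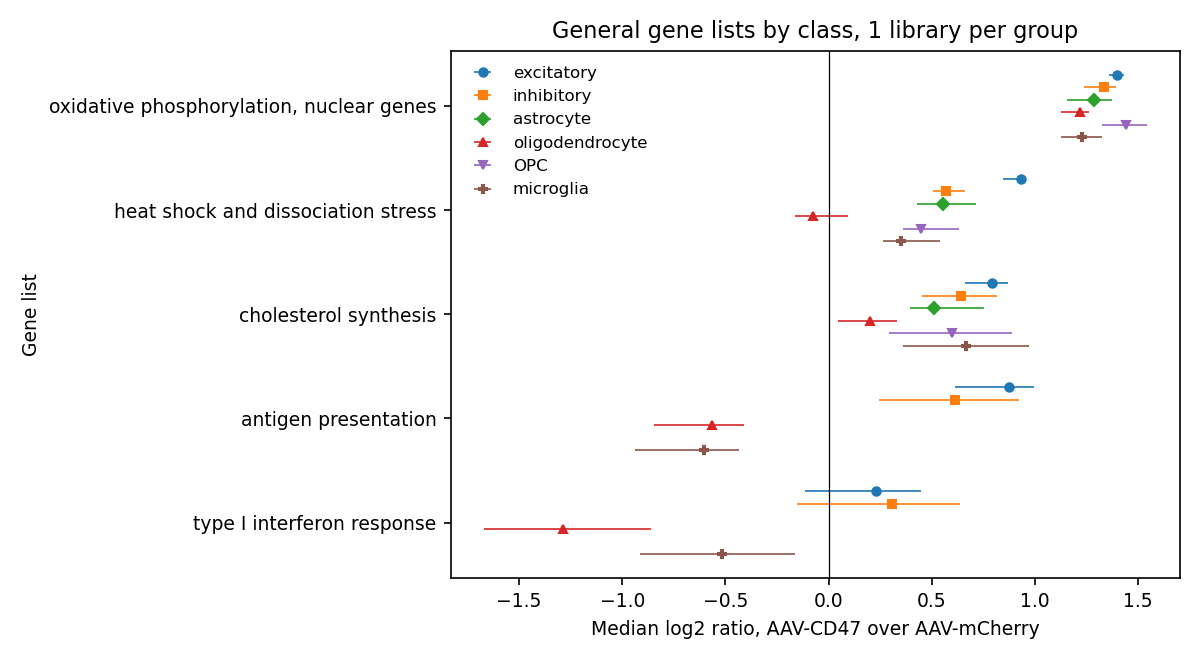
Median log2 ratio of AAV-CD47 over AAV-mCherry (horizontal axis) for 5 gene lists (vertical axis) in 6 classes shown by symbol and colour, with bars for the range over Poisson redraws of the counts. The oxidative phosphorylation list lies between 1.22 and 1.44 in all 6 classes, and the interferon list is lowest in oligodendrocytes at -1.29.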

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

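The signals in this part were picked after the data were examined. The shares of clusters 16 and 20 are also in the report, and cluster 10 served as the profile in a test of free RNA. None of these signals was itself tested and no explanation is offered.

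Haemoglobin genes, which stand for red blood cells, made up 59.33 CPM of the AAV-CD47 library and 1.13 CPM of AAV-mCherry, the control. Of 2496 Hbb-bs UMIs in AAV-CD47, 1479 lay in 2 nuclei.

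Cd47 was also higher in AAV-CD47 in the unnamed clusters of low UMI count. In cluster 9 it stood at 944.4 CPM in AAV-CD47 (719.0 to 1218), from 59 UMIs, and at 181.7 CPM in AAV-mCherry. In cluster 10 it stood at 1439 CPM in AAV-CD47 (1381 to 1499) and at 247.6 CPM in AAV-mCherry, above its level in CA2/CA3 neurons.

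Some unnamed clusters held more than 3 times the share of nuclei in AAV-CD47 that they held in AAV-mCherry. Cluster 10, led by Ttr, Sst, Npy and Chgb, held 7.935% against 0.858%. Cluster 13 held 3.833% against 0.999%, cluster 16, led by Cdh18 and Ccn2, held 4.728% against 0.982%, and cluster 24 held 3.851% against 0.19%. Cluster 20, led by the CA1 markers Wfs1 and Dcn, held 3.105% against 0.743%.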

How the results depend on the processing

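No paired analysis was possible because each group is 1 library and both carry replicate number 1. The alternatives chosen after seeing the data were automatic doublet thresholds, mixed clusters put in their nearest class, excitatory classes weighted equally, and values relative to the other classes; the others were planned. Among main results (shares, widths, chosen list medians and Cd47), 125 values under an alternative stayed within the main value's counting range, 56 moved out of it and 2 whose counting range excluded 0 changed sign; the microglial share, whose range included 0, is among those that moved and also changed sign. Among other lists and single genes, these numbers were 2519, 428 and 47. Over all alternatives with a value, Cd47 over all nuclei stayed between 1.159 and 1.325, the disease-associated list of microglia between -1.046 and -0.387, and the interferon list of oligodendrocytes between -1.351 and -1.001, with no value at a minimum of 200 UMIs per gene. With no filter on nuclei, unnamed clusters left out of the denominator or mitochondrial genes left out of totals, no value moved. With automatic doublet thresholds microglia had no value, and with the libraries clustered separately excitatory and CA2/CA3 neurons had no value. Thinning left out 2204 nuclei of AAV-mCherry and 85 of AAV-CD47. Among the 6 main classes depth was lowest in microglia, at medians of 1772 and 1935 UMIs per nucleus. Where values below differ from the main ones, the cause was not tested, except that the minimum of 200 UMIs leaves fewer genes and that the last setting subtracts a gene's median ratio over other classes.

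With at least 1000 UMIs per nucleus, the log2 share ratio was -0.172 for microglia, -0.53 for excitatory neurons, 0.419 for inhibitory neurons, 0.536 for astrocytes, -0.409 for oligodendrocytes and 0.206 for OPCs. With doublets kept, the log2 share ratio was 0.598 for astrocytes. The width was 1.293 in astrocytes, 1.26 in oligodendrocytes, 1.287 in OPCs and 1.365 in microglia. List medians were 0.34 for the homeostatic microglia list and -0.305 for the phagocytosis list in microglia. Log2 ratios were 0.46 for Ndst3 in OPCs. At Leiden resolution 0.5, the width was 1.238 in OPCs. Log2 ratios were 0.087 for Hs6st3 in OPCs. With automatic doublet thresholds, the width was 1.284 in inhibitory neurons, 1.718 in astrocytes and 1.64 in oligodendrocytes. List medians were 0.174 for the myelin list in oligodendrocytes. Log2 ratios were 0.043 for Gfap and 0.101 for Slc1a3 in astrocytes, and -0.363 for Sirpa and 0.215 for Apoe in oligodendrocytes. With the libraries clustered separately, the log2 share ratio was -0.019 for oligodendrocytes. With mixed clusters put in their nearest class, the width was 1.597 in microglia. List medians were 0.668 for the homeostatic microglia list in microglia. With the mean of single-nucleus CPM, the width was 1.545 in excitatory neurons, 1.295 in inhibitory neurons, 1.422 in astrocytes, 1.305 in OPCs and 1.427 in microglia. List medians were 1.45 for the oxidative phosphorylation list in excitatory neurons, and 0.365 for the homeostatic microglia list and -0.281 for the phagocytosis list in microglia. The log2 ratio was 1.325 for Cd47 over all nuclei. With the median ratio of the class set to 1, list medians were -0.304 for the excitatory synapse list, -0.206 for the autism risk list and 1.293 for the oxidative phosphorylation list in excitatory neurons. The log2 ratio was 1.159 for Cd47 over all nuclei. With a minimum of 200 UMIs per gene, the width was 1.333 in excitatory neurons, 1.078 in inhibitory neurons, 1.349 in astrocytes, 1.136 in oligodendrocytes and 1.241 in OPCs. List medians were -0.387 for the disease-associated microglia list in microglia. With nuclei thinned to 1000 UMIs, the width was 1.396 in excitatory neurons, 1.306 in inhibitory neurons, 1.541 in astrocytes, 1.285 in oligodendrocytes, 1.411 in OPCs and 1.472 in microglia. List medians were -0.172 for the excitatory synapse list in excitatory neurons, and 0.3 for the homeostatic microglia list in microglia. With excitatory classes weighted equally, the width was 1.514 in excitatory neurons. Relative to the other classes, the width was 0.609 in excitatory neurons, 0.697 in inhibitory neurons, 0.912 in astrocytes, 0.867 in oligodendrocytes, 0.833 in OPCs and 1.004 in microglia. List medians were 0.162 for the excitatory synapse list, 0.022 for the autism risk list, 0.032 for the ion channel list, 0.115 for the guidance and adhesion list and 0.109 for the oxidative phosphorylation list in excitatory neurons, and 0.007 for the excitatory synapse list, 0.112 for the autism risk list, 0.034 for the guidance and adhesion list and -0.015 for the oxidative phosphorylation list in inhibitory neurons, and -0.08 for the heat shock and dissociation stress list and -0.082 for the oxidative phosphorylation list in astrocytes, and -0.156 for the oxidative phosphorylation list and -0.393 for the cholesterol synthesis list in oligodendrocytes, and -0.116 for the heat shock and dissociation stress list in OPCs, and 0.025 for the homeostatic microglia list, -0.399 for the complement list, -0.097 for the heat shock and dissociation stress list and -0.016 for the oxidative phosphorylation list in microglia. Log2 ratios were 0.024 for Csmd2os, 0.228 for Angpt2, 0.215 for Grin2a, -0.115 for Gabra5, 0.173 for Cacna1c, 0.204 for Nrp1, -0.164 for Sirpa and 0.068 for P2ry12 in excitatory neurons, and -0.112 for Sirpa and -0.07 for Apoe in inhibitory neurons, and 0.001 for Slc1a3 in astrocytes, and -0.243 for Myl12b, -0.006 for Opalin and 0.041 for Nfasc in oligodendrocytes, and -0.23 for Apoe in OPCs, and -0.001 for Cox5a, -0.071 for Cox6c, -0.344 for C1qc, -0.399 for C1qb, -0.166 for Ctsl, 0.013 for Nfkb1, -0.033 for Dnaja1, -0.388 for Hsp90aa1, -0.324 for Bax, -0.017 for Atp5e and -0.173 for Hmgcs1 in microglia.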

Other observations

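Of the tests in this part, those chosen after the result was seen were the comparison of glia with neurons for energy genes, both tests of macrophages in microglia, and both comparisons of a list with the other classes. The remaining ones were set before their result was seen.

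The neuronal classes differed in how far some gene groups lay above AAV-mCherry, differences that were not tested. Genes of heat shock and dissociation stress had a median log2 ratio of 1.18 in CA2/CA3 neurons and 0.81 in dentate granule neurons. They were at 0.71 in CA1 neurons and 0.57 in inhibitory neurons. These medians rest on 9, 11, 11 and 8 measured members, so on partly different genes. Glia were mostly higher too, with this list at 0.55 in astrocytes, 0.45 in OPCs, 0.35 in microglia and -0.07 in oligodendrocytes. These rest on 7, 7, 8 and 10 measured members. Cholesterol synthesis genes stood at 0.99 in CA2/CA3 neurons, 0.50 in dentate granule neurons, 0.54 in CA1 neurons and 0.64 in inhibitory neurons. In glia they stood at 0.67 in microglia, 0.60 in OPCs, 0.51 in astrocytes and 0.20 in oligodendrocytes. Activity-regulated genes stood at 0.67 in dentate granule neurons, 0.51 in CA2/CA3 neurons, 0.39 in CA1 neurons and 0.54 in inhibitory neurons. Tissue handling may raise the heat shock and dissociation stress genes and the activity-regulated genes, and it was not tested as a cause. Antigen presentation genes of oligodendrocytes had a median of -0.56 over 5 measured members.

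Transcripts typical of further cell types were read as well, and their origin was not tested. The pancreatic protease gene Ctrb1 had 201 UMIs in AAV-mCherry and 197 in AAV-CD47, in 2 nuclei of each library. Igkc, an immunoglobulin light chain gene of B lineage cells, had 14562 and 4109 UMIs. Gabra6, a marker of cerebellar granule cells, had 49 and 15 UMIs. Igkc led unnamed cluster 34, with 77 AAV-mCherry and 35 AAV-CD47 nuclei. Gabra6 was among the leading genes of unnamed cluster 2, with 41 and 3 nuclei.

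Nuclear genes of oxidative phosphorylation were higher in AAV-CD47 in all classes, and 3 explanations were weighed. A response of neurons to CD47 stays open. The median of 3 glial list medians was 0.882 times that of excitatory neurons, but this was part of the pattern that prompted the test, and free RNA would carry a neuronal rise into glia. A difference in depth stays open. Thinning kept 0.981 times the list median, but it leaves a gene's expected share of the UMIs unchanged, so it cannot decide. For free RNA carried by all droplets, the share of a low-UMI profile that glia would need for these genes was 4.485 times the share needed for Sst, Npy, Chgb and Ttr, past the bound of 3 set beforehand against it. With that profile, free RNA would have to supply 42.1% of AAV-CD47 UMIs in microglia, 32.3% in oligodendrocytes, 28.5% in astrocytes and 25.3% in OPCs. For Sst, Npy, Chgb and Ttr the shares were 9.19%, 6.33%, 6.90% and 5.76%. These large shares go against free RNA of that profile. The bound was wrong, since no deposited barcode holds fewer than 500 UMIs and the profile was assumed from cluster 10. Free RNA of another make-up, along with library preparation, may therefore still account for the pattern.

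Disease-associated genes were lower in the microglia of AAV-CD47. For the 13 of 20 members that other classes also measured, free RNA is argued against, because their median there was 0.218, in the other direction. Igf1 and Axl had no such value. A ratio in other classes also holds their own RNA, such as Apoe in astrocytes, so it does not measure free RNA alone. Thinning kept 0.982 times the list median, but it leaves a gene's expected share unchanged, so a difference in depth stays open. For Gpnmb by itself free RNA stays open, because its median log2 ratio over the other classes was -0.696. That is in the same direction as in microglia but much smaller than the -6.72 there. Border macrophages within the class and a change in microglia cannot be told apart, because 2 tests of macrophages went different ways. Summed macrophage markers were lower by more than the list, with a log2 ratio of -2.81 (-4.78 to -1.31), while without the 21 and 3 nuclei that held such a UMI the list median was still -0.792; this second test was added once the first had come out for macrophages, and it misses those with no marker UMI. After this removal AAV-mCherry kept 53 of 113 Gpnmb UMIs, 843 of 987 Apoe UMIs and 122 of 151 Cd74 UMIs, against 1, 227 and 4 UMIs in AAV-CD47. A response of microglia to CD47, and a difference between the animals, are open and untested hypotheses.

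Interferon-response genes were lower in the oligodendrocytes of AAV-CD47. Microglia and T cells within the class are argued against, because their summed markers there had a log2 ratio of -0.049 (-0.25 to 0.15), above the list median of -1.29. Summed B cell markers, read after this result, were higher in AAV-CD47, with 18 and 46 UMIs and a log2 ratio of 1.66 (0.846 to 2.534). Their list includes Ebf1, also a leading gene of unnamed cluster 29, which is nearest to endothelial cells. Unnamed cluster 34, nearest to B cells and led by Igkc, held 77 AAV-mCherry and 35 AAV-CD47 nuclei. The marker sum therefore does not decide on B cells, and other immune types were not tested. Free RNA is argued against by the median of 0.339 in other classes, which rests on only 4 members. A state of some animals, such as an infection or a response to the virus, may differ between the libraries, and with 1 library per group it stays open and untested beside the AAV-CD47 treatment.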
